A study of Homo sapiens with 40 samples.

How the data were processed

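The series holds 40 deposited samples from 20 RNA samples, each of which was measured on both arrays of the Affymetrix HG-U133 pair, A and B. Per the labels' protocols, monocytes of healthy volunteers were incubated in serum with or without interferon alpha 2b, and RNA was isolated with either of 2 kits, the choice depending on the number of cells recovered. The labels do not say which sample was isolated with which kit. Per the labels' protocols the RNA was then labelled with biotin in 2 cycles of amplification, which favours the 3' ends of transcripts. Titles separate 2 culture sets, each with every treatment and time, by an added term that only the titles of set 2 carry. The labels do not explain this term. The labels do not say that the sets come from separate volunteers, so p-values here measure spread between these samples and not between people in general.

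The deposited values are a linear signal intensity per probe set and array. Their trimmed means (2% left out at each end) lay between 500.192 and 500.26 on array A and between 500.185 and 500.266 on array B, so the deposited intensity had been scaled to a common mean near 500. The software and method that produced it are not given in the sources used here. Intensities ran from 0.2 to 132425 on array A and from 0.5 to 341284 on array B. Present or absent calls were not used here. Some items are not reported here.

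All choices of filters, tests, comparisons, gene lists and rules for naming genes were made before the data were examined, except where a sentence says otherwise. Intensities under the 20th percentile of a table (24 on array A and 50.2 on array B) were set to that value and log2-transformed. Array medians spanned 0.452 on the log2 scale on array A and 0.412 on array B, under the limit of 0.5 set beforehand for quantile normalization, so the deposited scale was kept. Between 17.7% and 22.5% of probe sets per array lay at the floor on array A, and between 16.0% and 23.8% on array B. Probe sets above the table's median (126.3 and 212.2) in at least 2 arrays were tested, without the 68 control probe sets of each array, which left 15177 of 22283 on array A and 17918 of 22645 on array B. Genes were taken from the platform annotation tables at GEO, with symbols updated through the gene identifiers. On array A 19071 probe sets had 1 symbol, 1043 several and 2169 none, and on array B 15432, 554 and 6659. The probe sets tested with 1 symbol stood for 8994 genes on array A and 8324 on array B.

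The 2 arrays were fitted apart with limma 3.58.1 in R 4.3.3: a linear model with the 10 conditions and the culture set as a block, moderated with an intensity trend, on all 20 arrays of a table. Adjusted p-values are those of Benjamini and Hochberg within each array and comparison, and calls were made under 0.05. The 9 residual degrees of freedom were joined by a prior of 7.26 on array A and 12.6 on array B. Comparisons were interferon against serum at each of the 5 times and averaged over them, serum alone at 6 hours and 3 days against 1 hour, an F test of differences between the 5 interferon effects, and a test of the difference of the averaged effect between sets. The set served as a block because the series describes cultures divided between the 2 treatments. In a check of this pairing, differences between the sets in serum and in interferon samples of the same time correlated across probe sets at 0.211 to 0.481 on array A and 0.136 to 0.257 on array B. All 45 pairs of conditions, whatever the time, gave 0.0891 to 0.485 (median 0.164) and 0.0696 to 0.306 (median 0.104). Each value of the same time lay within that range and above that median. Probe sets shared by the 2 arrays correlated with the namesake array of the same sample at a median of 0.859, and 19 of 20 samples matched their own namesake best.

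The procedure was tested on simulated data in which 100 probe sets changed by 1 and another 100 by 2 on the log2 scale. At 6 hours, a change of 1 was found for 1% of its 100 probe sets on either array. A change of 2 was found for 27% on array A and 13% on array B, with 1 false call on array A and 0 on array B. For the average over times these were 49% and 92% on array A and 30% and 82% on array B, with 6 false calls in each case, and data without change gave 0. In these simulated data, changes of up to 2 on the log2 scale at 6 hours were therefore mostly missed. The simulation held no larger changes and drew its noise independently for each array. Its rates of recovery and of false calls may therefore differ from those in the real data.

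Genes were named by a rule: per comparison, the called probe sets of 1 gene with the greatest absolute difference and the same direction in both sets (8 higher and 4 lower on array A, 4 and 2 on array B, for each time; 12, 8, 5 and 5 over all times, with at least 9 of 10 pairs in the same direction; 8, 8, 3 and 3 for serum), and per gene list the 4 called members with the greatest difference. Where a gene has several probe sets, the text gives a probe set picked by these rules, which is not always that of the greatest difference. Genes of the sex chromosomes that tell sexes apart were left out of the naming. The text names a part of these genes, with preference for those that kept their call without any single sample; that preference was set after the data were seen.

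The 32 gene lists were tested on array A with 1 probe set per gene, that of the highest mean signal, using camera of limma with a preset correlation of 0.01, adjusted over the 32 lists within a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. The lists were interferon-stimulated genes, interferon signalling, MHC class I and class II presentation, interferon-linked chemokines, inflammatory cytokines, anti-inflammatory and feedback genes, the migratory dendritic cell programme, monocyte markers, macrophage maturation, Fc receptors and complement, cell death, lymphocyte-stimulating cytokines, nucleic acid and pathogen sensors, immediate-early genes, heat shock genes, metallothioneins, glycolysis and hypoxia, cholesterol and lipid metabolism, mitochondrial respiration, cytosolic ribosomal proteins, cell cycle, tryptophan, arginine and NAD metabolism, adhesion and migration, and markers of T cells, B cells, NK cells, platelets, erythroid cells, neutrophils, plasmacytoid dendritic cells, and basophils and mast cells. Counts of members include genes measured on array B alone.

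RNA quality was read from control probe sets (3' over 5' ratios of GAPDH and ACTB, ribosomal RNA) and compared between treatments with an exact sign-flip permutation test over the 10 pairs of set and time, adjusted over 16 measures. Alternatives were quantile normalization, median centring, a pseudocount instead of the floor, a floor at the 40th percentile, no filter, a filter at the 75th percentile, moderation without the trend, no block, a block for each of the 10 pairs, only the 4 arrays of a time (or the 10 serum arrays), a minimum log2 difference of 1, each sample left out in turn, each set alone, and for lists the median over a gene's probe sets. Exclusions of the 3 samples of highest GAPDH ratio, of 24 hours and of 2 and 3 days were chosen after the data were seen. Where a sample is left out, its partner is assumed to vary like the samples of the other groups. Its condition then holds 1 sample, so a lost call can come from lost replication as well as from that sample. The 2 sets differ in GAPDH ratio, so leaving out a set changes RNA quality as well. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.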

Results

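Monocytes from the blood of healthy volunteers were kept in medium with 20% autologous serum, either alone or with 1000 U/ml of interferon alpha 2b (IFNα2b), a type I interferon. Cells were harvested after 1 hour, 6 hours, 24 hours, 2 days and 3 days, so that the series asks which transcripts interferon induces at each time. Each of the 10 conditions held 2 samples, told apart by their titles and called here culture set 1 and culture set 2. RNA of each sample was hybridised to 2 arrays of the HG-U133 pair, array A with 22283 probe sets and array B with 22645, which gave 20 arrays per table and 40 in all. After low signals were removed, 15177 probe sets on array A and 17918 on array B were tested. The small number of arrays per condition limits the precision. Values below are log2 differences with their standard errors, followed by the fold, from n = 2 samples per group unless stated. A fold against a group that lay wholly at the floor is given as at least that size. A fold against a group with only some samples at the floor carries no such mark, though it is a lower bound too. Among these are RSAD2 of array A at 6 hours and IFI44L at 3 days, each with 1 of 2 serum samples at the floor. USP18 over all times had 4 of 10 serum samples there.

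After 1 hour, interferon-stimulated transcripts were already far higher with interferon. IFIT1, whose product binds viral RNA, rose from signals of 27.1 and 219 in serum to 7722 and 21266 (7.38 ± 1.03, 166-fold). Its relatives IFIT2 (5.95 ± 0.70, 61.8-fold) and IFIT3 (5.50 ± 0.49, 45.4-fold), the antiviral gene IFI44 (6.39 ± 0.64, 83.9-fold) and the monocyte attractant CCL8 (6.85 ± 0.89, 116-fold) rose with it. On array B the antiviral RSAD2 (6.14 ± 0.88, 70.3-fold), ACOD1, whose enzyme makes itaconate (5.40 ± 0.52, 42.3-fold), and the checkpoint ligand CD274 (5.51 ± 0.62, 45.6-fold) rose. The RSAD2 probe set of array A rose as well (6.72 ± 1.04, 105-fold), a call that ended without the serum sample of set 1 (6.45, adjusted p = 0.0587), the interferon sample of set 2 (6.05, adjusted p = 0.145) or the filter on low signals (adjusted p = 0.0644). The CXCR3 ligands CXCL10 (7.34 ± 1.03, 162-fold) and CXCL11 (6.32 ± 0.96, 79.9-fold) also rose. Without the serum sample of set 2 these stood at 6.12, adjusted p = 0.0628 and 5.14, adjusted p = 0.0970, and without the interferon sample of set 2 CXCL11 stood at 6.29, adjusted p = 0.0872. Fewer transcripts fell: TPP1, a lysosomal peptidase (-3.91 ± 0.71, 15.0-fold lower), LLPH (-2.92 ± 0.55, 7.55-fold lower) and, on array B, PPP1R3E (-2.66 ± 0.49, at least 6.34-fold lower). All 3 calls ended without single samples of that time, those of TPP1 and LLPH without any of the 4. Such a removal leaves 1 sample in a group, so lost replication can end a call by itself. Without each sample whose removal ended the call, TPP1 ranged from -4.18 to -3.63, adjusted p 0.113 to 0.171, LLPH from -3.22 to -2.62, adjusted p 0.0939 to 0.201 and PPP1R3E from -2.68 to -2.27, adjusted p 0.0543 to 0.211. With a floor at the 40th percentile the 3 stood at -2.52, adjusted p = 0.182, -1.35, adjusted p = 0.131 and -1.14, adjusted p = 0.423, and with only the 4 arrays of the time their adjusted p was 0.0619, 0.230 and 0.590. TPP1 also lost its call without the intensity trend of limma (adjusted p = 0.0626), without the filter on low signals (0.0985) and without the 3 samples of highest GAPDH ratio, all of 2 or 3 days (0.0668), and CXCL11 lost its call without the filter (0.0502).

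Of the 57 interferon-stimulated genes measured, 25 rose and none fell after 1 hour, and 42 rose when adjusted over the list alone. The list's median was 1.96, with a camera adjusted p of 9.92e-69 and, with an estimated correlation, an adjusted p of 0.0127. Of 8 interferon-linked chemokines 4 rose (4 adjusted over the list alone). That list's adjusted p was 3.79e-12, and 0.0127 with an estimated correlation. Of 31 nucleic acid and pathogen sensors 4 rose (5 over the list alone), RIGI and IFIH1 foremost (4.91 ± 0.81 and 3.44 ± 0.50; median 0.53, adjusted p = 6.87e-10; 0.0428 with an estimated correlation). The RIGI call ended without the serum sample of set 1 (3.83, adjusted p = 0.146) or the interferon sample of set 2 (4.54, adjusted p = 0.190), as did that of IFIH1 (2.98, adjusted p = 0.0587 and 2.61, adjusted p = 0.126). RIGI had an adjusted p of 0.0772 without the filter and 0.151 without culture set as a block. No member of the MHC class I list passed the test (median 0.09, camera adjusted p = 0.319, 1 member adjusted over the list alone). On array A 58 probe sets were higher and 12 lower, and on array B 72 and 18. On array A 15 were called without the interferon sample of set 2 and 34 without the serum sample of set 2, and on array B 57 without the serum sample of set 1 and 39 without that of set 2. Moderation without the trend gave 43 and 33, leaving out the 3 samples of highest GAPDH ratio 43 and 58, and only the 4 arrays of the time 57 on array B. Without culture set as a block 26 and 42 were called. Of the 18 genes picked by rule 5 then lost their call (IFIT1, CXCL10, CXCL11, RBM19 and USP4, adjusted p 0.0578 to 0.146).

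After 6 hours the response had its largest counts. RSAD2 (8.36 ± 1.04, 329-fold), the deubiquitylase USP18 (7.54 ± 0.68, at least 186-fold), the exonuclease ISG20 (7.38 ± 1.11, 166-fold), the RNA sensor relative DHX58 (6.68 ± 0.41, 102-fold) and IFIT1 (6.47 ± 1.03, 88.5-fold) rose. CXCL11 (7.42 ± 0.96, 171-fold), CCL8 (6.88 ± 0.89, 118-fold) and CXCL10 (6.69 ± 1.03, 103-fold) did so too. On array B the guanylate-binding protein GBP5 (6.26 ± 0.69, 76.6-fold), NEXN, an actin-binding protein (6.60 ± 0.54, 96.9-fold), and the ubiquitin ligase RNF213 (6.03 ± 0.76, at least 65.3-fold) rose. MRPS27 (-3.30 ± 0.45, at least 9.87-fold lower) and NARS2 (-2.93 ± 0.50, 7.65-fold lower), both of mitochondrial translation, the lipase ABHD2 (-3.29 ± 0.43, 9.79-fold lower) and the tRNA exporter XPOT (-3.57 ± 0.55, 11.8-fold lower) fell. The aldo-keto reductase AKR1C3 fell as well (-3.47 ± 0.73, 11.1-fold lower), a call that ended without the serum sample of set 1 (-2.95, adjusted p = 0.171) and without either interferon sample (-3.75, adjusted p = 0.0771 without set 1; -3.20, adjusted p = 0.108 without set 2) or with a filter at the 75th percentile (adjusted p = 0.138). With a floor at the 40th percentile the calls of MRPS27 (-1.54, adjusted p = 0.0783) and NARS2 (-1.20, adjusted p = 0.288) ended, and with only the 4 arrays of the time that of XPOT (adjusted p = 0.0772).

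By group, 53 of the 57 interferon-stimulated genes rose at 6 hours and all 57 when adjusted over the list alone (median 4.04, camera adjusted p = 1.04e-100; 0.00635 with an estimated correlation). Among 19 MHC class I genes 5 rose (9 adjusted over the list alone), with the peptide transporter TAP1 at 2.27 ± 0.41 and the regulator NLRC5 at 3.28 ± 0.43. Their list's adjusted p was 1.84e-09, or 0.0102 with an estimated correlation. Sensors counted 9 risen of 31 (12 over the list alone), with RIGI at 5.55 ± 0.81, IFIH1 at 3.60 ± 0.50 and the restriction factor APOBEC3G at 3.17 ± 0.40. The adjusted p of the sensors was 7.34e-13, or 0.0132 with an estimated correlation. In the cell death list 4 of 28 rose (5 over the list alone): the death ligand TNFSF10 (5.82 ± 0.77), XAF1 (3.43 ± 0.53), the pore former GSDMD (2.97 ± 0.47) and CFLAR, which inhibits death signalling (1.86 ± 0.45; 1.44, adjusted p = 0.237 without the serum sample of set 1, and 1.24, adjusted p = 0.288 without the interferon sample of set 2). The list's adjusted p was 6.32e-06, or 0.0325 with an estimated correlation. Lymphocyte-stimulating cytokines counted 5 risen of 15 (5 over the list alone), with IL15 at 3.53 ± 0.54, its receptor IL15RA at 3.82 ± 0.48 and TNFSF13B, the B cell factor BAFF, at 3.02 ± 0.46. For these cytokines the adjusted p of 2.41e-04 became an adjusted p = 0.0628 with an estimated correlation. Without the set as a block GSDMD (adjusted p = 0.208), CFLAR (0.281) and TNFSF13B (0.112) lost their call. TNFSF13B also lost it with only the 4 arrays of the time (0.192), and CFLAR with quantile normalization or without the trend, the filter or the 3 samples of highest GAPDH ratio (adjusted p 0.0732 to 0.113). Of 10 heat shock genes 3 rose (5 over the list alone): HSPB1, HSPH1 and DNAJA1, each call lost on leaving out some single sample, that of DNAJA1 on leaving out the serum sample of set 2, the interferon sample of set 1 or either serum sample at 2 days (0.94 to 1.75, adjusted p 0.0502 to 0.370). The heat shock median was 1.18 (adjusted p = 7.69e-09, and 0.0325 with an estimated correlation). Over those removals HSPB1 ranged from 1.95 to 4.12, adjusted p 0.0995 to 0.278 (serum of set 1 and both interferon samples), and HSPH1 from 1.42 to 1.71, adjusted p 0.0943 to 0.106 (serum of set 2 and interferon of set 1).

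Among markers of other blood cells the platelet list had a median of -1.13 at 6 hours, with means of -1.71 in set 1 and -0.75 in set 2, no member called of 9 and an adjusted p of 0.0788. At 6 hours 290 probe sets were higher and 87 lower on array A, and 161 and 36 on array B. The median of all tested probe sets on array A lay at -0.152, so the lower side in particular is relative to that shift. With each array centred on its median, 321 were higher and 58 lower on array A, and 163 and 20 on array B. Without the interferon sample of set 1 the counts were 212 and 120. Without the set as a block they were 195 (173 higher) and 95, and with each pair of set and time as a block 634 (400 higher) and 363 (253 higher). They were 235 and 78 without the trend, and 625 (441 higher) and 74 from only the 4 arrays of the time.

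**Figure D1:**
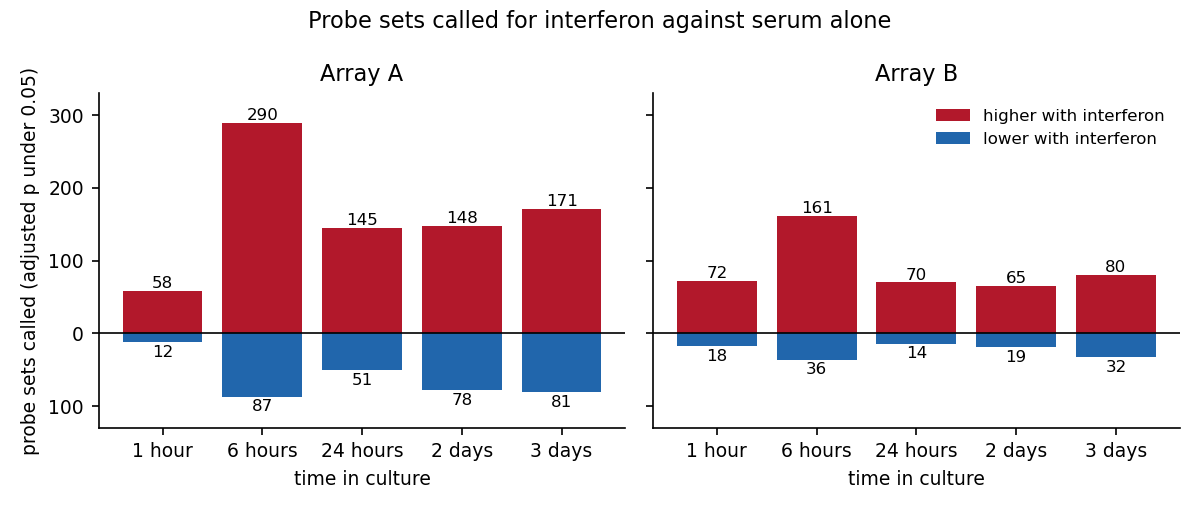
Number of probe sets called at each time for interferon against serum alone (limma, adjusted p under 0.05), with higher counts above 0 and lower counts below it, on array A (left) and array B (right). The counts were highest at 6 hours, with 290 higher and 87 lower on array A and 161 and 36 on array B.

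At 24 hours the antiviral genes RSAD2 (5.50 ± 1.04, 45.2-fold), RIGI (5.19 ± 0.81, 36.4-fold), IFI44L (5.06 ± 1.00, 33.3-fold) and IFIT1 (5.03 ± 1.03, 32.7-fold), the tryptophan-degrading enzyme IDO1 (4.80 ± 0.94, 27.9-fold) and, on array B, GBP5 (4.38 ± 0.69, 20.9-fold) rose. The fatty acid-binding protein FABP4 (-4.94 ± 1.00, 30.7-fold lower), PID1, an adaptor of the insulin pathway (-4.43 ± 0.63, 21.6-fold lower), and the myeloid receptor CLEC5A (-3.55 ± 0.58, 11.7-fold lower) fell. Every one of these calls ended without some single sample of that time, which leaves 1 sample in its group. Without the serum sample of set 1 the differences of PID1 and CLEC5A kept their size, while those of the induced genes shrank. The serum sample of set 2 held the interferon-induced transcripts at levels far above those of set 1 (IFIT1 signals of 3185 and 102). Without that sample the calls of RSAD2 (7.76), RIGI (6.80), IFI44L (7.44), IFIT1 (6.75), IDO1 (6.26) and GBP5 (6.17) stayed, with differences larger by over 1 on the log2 scale. Leaving out the set 1 serum sample leaves the sample of set 2 as the only serum sample. This brought RSAD2 to 3.23, adjusted p = 0.248, RIGI to 3.57, adjusted p = 0.113 and IFI44L to 2.68, adjusted p = 0.285. It brought IFIT1 to 3.31, adjusted p = 0.378, and IDO1 to 3.34, adjusted p = 0.319. It also brought GBP5 to 2.60, adjusted p = 0.118, PID1 to -4.47, adjusted p = 0.0579 and CLEC5A to -3.71, adjusted p = 0.0840. Without the interferon sample of set 1 the values were 4.96, adjusted p = 0.184 for RSAD2, 4.51, adjusted p = 0.0885 for RIGI and 4.50, adjusted p = 0.231 for IFI44L. They were 4.16, adjusted p = 0.290 for IFIT1, 2.65, adjusted p = 0.275 for IDO1, 3.66, adjusted p = 0.162 for GBP5 and -3.67, adjusted p = 0.0596 for PID1. Without the interferon sample of set 2 IFI44L stood at 5.62, adjusted p = 0.0512 and CLEC5A at -2.72, adjusted p = 0.0629. The FABP4 call ended without any of 3 samples, both serum samples and the interferon sample of set 2 (-5.08 to -3.58, adjusted p 0.143 to 0.206). Without the trend the calls of RSAD2, IFI44L, IFIT1, IDO1, FABP4 and GBP5 ended (adjusted p 0.0587 to 0.0868), as they did without the filter (0.0601 to 0.151). With only the 4 arrays of the time all 9 ended (0.183 to 0.344), and without the 3 samples of highest GAPDH ratio that of IDO1 (0.0593).

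As a group the interferon-stimulated genes stayed higher at 24 hours, with 45 of 57 risen (56 adjusted over the list alone) and a median of 2.93 (camera adjusted p = 5.49e-84; 0.0125 with an estimated correlation). That median was 3.86 without the serum sample of set 2 and 2.17 without that of set 1. Sensors counted 6 risen of 31 (11 over the list alone; adjusted p = 2.17e-10, and 0.0349 with an estimated correlation). MHC class I genes counted 2 risen of 19 (4 over the list alone; adjusted p = 1.00e-07, and 0.0228 with an estimated correlation). Among 35 macrophage maturation genes 2 fell, FABP4 and its relative FABP5 (-2.79 ± 0.54; -2.83 to -1.92, adjusted p 0.0985 to 0.181 without either serum sample or the interferon sample of set 2), and 9 fell and 2 rose when adjusted over the list alone. Their median was -1.04, and the camera adjusted p of 8.67e-05 became an adjusted p = 0.286 with an estimated correlation. Without the interferon sample of set 2 it was -0.37, adjusted p = 0.129. On array A 145 probe sets were higher and 51 lower, and on array B 70 and 14. With each array centred on its median the split on array A was 185 higher and 33 lower, and on array B 76 and 7. The counts on arrays A and B were 11 and 12 without the serum sample of set 1 and 30 and 17 without the interferon sample of set 1, and on array A 124 without the serum sample of set 2. Dropping the block for sets left 69 and 35 calls, and 9 of the 18 genes picked by rule lost their call, RIGI, IFI44L, IFIT1 and FABP4 among them (adjusted p 0.0624 to 0.308). Of the 18, 14 lost their call without the trend, 15 without the filter and 18 with only the 4 arrays of the time, and FABP5 lost its call in each of these 3 fits (adjusted p 0.0705 to 0.183). With each pair of set and time as a block 378 (240 higher) and 183 (129 higher) were called, without the trend 89 and 0, without the filter 94 and 36, and from only the 4 arrays of the time none.

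At 2 days interferon-stimulated genes remained higher. ISG20 (7.05 ± 1.11, 133-fold), IFIT1 (6.82 ± 1.03, 113-fold), IFI44L (6.71 ± 1.00, 105-fold), the ubiquitin-like ISG15 (5.61 ± 0.71, 48.7-fold), IFIT2 (5.10 ± 0.70, 34.3-fold) and, on array B, IFIT3 (5.68 ± 0.52, 51.2-fold) and GBP5 (5.01 ± 0.69, at least 32.2-fold) rose. So did CCL8 (6.31 ± 0.89, 79.3-fold). The falls included genes that rose in serum alone by 3 days: FABP4 (-5.65 ± 1.00, 50.4-fold lower), CHI3L1, a chitinase-like protein of macrophages (-5.54 ± 0.83, at least 46.4-fold lower), and lipoprotein lipase LPL (-5.48 ± 1.09, 44.5-fold lower). The transcription factor BHLHE41 (-4.98 ± 0.85, 31.6-fold lower) and, on array B, ABHD2 (-3.62 ± 0.53, 12.3-fold lower) fell. Of 2 other CHI3L1 probe sets 1 went the other way. These calls rested on set 2. Without the serum sample of set 2 FABP4 stood at -4.27, adjusted p = 0.187, and CHI3L1 at -4.88, adjusted p = 0.0632. LPL stood at -3.94, adjusted p = 0.355 and BHLHE41 at -4.12, adjusted p = 0.141. Without the interferon sample of set 2 FABP4 stood at -3.86, adjusted p = 0.140, and LPL at -3.44, adjusted p = 0.258. BHLHE41 then stood at -4.62, adjusted p = 0.0688 and ABHD2 at -2.73, adjusted p = 0.0678. LPL and ABHD2 lost their call without the trend (adjusted p = 0.0616 and 0.0738), and FABP4 and LPL without the filter (0.0658 and 0.109). With only the 4 arrays of the time IFIT3, GBP5, FABP4, LPL and ABHD2 lost theirs (0.104 to 0.276). The 2 samples of set 2 at 2 days, with the interferon sample of set 2 at 3 days, had the highest 3' over 5' ratios of GAPDH on array A. These were 3.01 (serum, 2 days), 3.76 (interferon, 2 days) and 3.31 (interferon, 3 days) on the log2 scale, a sign of RNA degradation or short cDNA. The ratio also parted the sets at all times. On array A it ran from 0.783 to 1.62 in set 1 and from 1.87 to 3.76 in set 2. On array B it ran from 1.28 to 1.77 and from 1.84 to 3.94. Culture set and RNA quality therefore cannot be told apart, and leaving out 3 samples does not remove this difference.

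In the macrophage maturation list 5 of 35 fell at 2 days and 16 when adjusted over the list alone (median -1.30). The camera adjusted p of 5.73e-12 became an adjusted p = 0.0810 with an estimated correlation. Of the 57 interferon-stimulated genes 49 rose (54 over the list alone; median 3.65; adjusted p = 1.83e-86, and 0.0112 with an estimated correlation). Among 6 metallothioneins 3 rose (4 over the list alone; median 1.83; adjusted p = 8.89e-07, but adjusted p = 0.0766 with an estimated correlation). On array A 148 probe sets were higher and 78 lower, and on array B 65 and 19. Counts on the 2 arrays were 97 and 28 without the serum sample of set 1, 84 and 35 without that of set 2, and 104 and 33 without the interferon sample of set 2. Leaving out the 3 samples of highest GAPDH ratio, an exclusion chosen after the ratios were seen, removes both set 2 samples of 2 days. The comparison then rests on 1 sample per group, both of set 1, so RNA quality cannot be told apart from lost replication. Most genes picked by rule then lost their call, among them ISG20, CCL8, ISG15, GBP5, FABP4, CHI3L1, LPL, BHLHE41 and ABHD2. The log2 differences of those that lost it stood between -4.98 and 7.41. The model with no block for sets called 111 and 38, and ABHD2 was lost (adjusted p = 0.0860). With each pair as a block 384 (214 higher) and 182 (116 higher) were called, without the trend 140 and 18, without the filter 145 and 40, and from only the 4 arrays of the time 81 and 0.

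At 3 days antiviral genes were still far higher with interferon. IFIT1 (9.66 ± 1.03, at least 807-fold), RSAD2 (9.09 ± 1.04, at least 544-fold), IFI44L (9.02 ± 1.00, 518-fold), the membrane protein IFITM1 (8.05 ± 0.99, 264-fold) and IFI27 (7.13 ± 0.76, 140-fold) rose, as did CCL8 (6.76 ± 0.89, 108-fold). In serum alone, 3 days against 1 hour gave -1.68 ± 1.03 for IFIT1, -2.86 ± 1.04 for RSAD2, -5.04 ± 1.00 for IFI44L and -3.23 ± 0.99 for IFITM1. IFI27 stood at -0.40 ± 0.76. An interferon difference larger than at 1 hour therefore need not mean a stronger induction. On array B RSAD2 (7.97 ± 0.88, 252-fold), IFIT3 (6.79 ± 0.52, 111-fold), IFIT2 (5.92 ± 0.58, 60.7-fold) and RNF213 (5.31 ± 0.76, at least 39.6-fold) rose. GCH1, the first enzyme of tetrahydrobiopterin synthesis (4.82 ± 0.65), the transcription factor IRF7 (3.99 ± 0.58) and the complement inhibitor SERPING1 (4.16 ± 0.55) were also up. ITGAM, the integrin chain CD11b, fell (-3.36 ± 0.42). CHI3L1 (-5.52 ± 0.83, 45.9-fold lower), the protease inhibitor TIMP3 (-5.30 ± 0.94, 39.4-fold lower), FABP4 (-5.19 ± 1.00, 36.5-fold lower) and LPL (-4.89 ± 1.09, 29.7-fold lower) fell. Each of these calls ended without some single sample of that time. Without the serum sample of set 2 they stood at -4.35, adjusted p = 0.0762 (CHI3L1), -4.42, adjusted p = 0.173 (TIMP3), -4.50, adjusted p = 0.216 (FABP4) and -3.38, adjusted p = 0.494 (LPL). Without the interferon sample of set 1 TIMP3 stood at -5.11, adjusted p = 0.0770, FABP4 at -4.56, adjusted p = 0.164 and LPL at -4.47, adjusted p = 0.240, and without that of set 2 LPL stood at -5.32, adjusted p = 0.125. LPL lost its call without the trend (adjusted p = 0.0967) or the filter (0.150), and FABP4 without the filter (0.0879). With only the 4 arrays of the time CHI3L1, IRF7, ITGAM and, on array B, RSAD2, IFIT3, IFIT2 and RNF213 lost theirs (0.0508 to 0.273).

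Of the 57 interferon-stimulated genes 52 rose at 3 days (56 over the list alone; median 3.86; camera adjusted p = 1.71e-94, and 0.00808 with an estimated correlation). In the macrophage maturation list 5 of 35 fell, and 11 adjusted over the list alone (median -0.83); the adjusted p of 2.35e-08 became an adjusted p = 0.182 with an estimated correlation. The monocyte markers gave 1 fall of 18, ITGAM, and 5 adjusted over the list alone (median -0.73, adjusted p = 0.00271; adjusted p = 0.254 with an estimated correlation). That call ended without the serum sample of set 1 (-0.10, adjusted p = 0.507) or the interferon sample of set 1 (-0.14, adjusted p = 0.0614). The cholesterol and lipid list had 1 fall of 21, LPL, also 1 over the list alone (median -0.51, adjusted p = 0.00208; adjusted p = 0.140 with an estimated correlation), and this call ended without the interferon sample of set 1 (-0.42, adjusted p = 0.0596). On array A 171 probe sets were higher and 81 lower, and on array B 80 and 32. With each array centred on its median these were 178 and 65 on array A, and 84 and 21 on array B. Leaving out the serum sample of set 2 gave 95 and 42, the interferon sample of set 1 gave 92 and 40, that of set 2 gave 119 and 49, and on array B the serum sample of set 1 gave 50. Without the 3 samples of highest GAPDH ratio 109 and 46 were called, and 5 of the 18 genes picked by rule lost their call. CHI3L1 then stood at -4.96, adjusted p = 0.0726, FABP4 by its probe set on array B at -3.96, adjusted p = 0.325, and IRF7 of the gene lists at 3.44, adjusted p = 0.0532. Without the set as a block 117 and 41 were called, and 4 of the 18 genes picked by rule lost their call, LPL among them (adjusted p 0.0525 to 0.0746). With each pair as a block 431 (260 higher) and 207 (123 higher) were called, without the trend 155 and 24, from only the 4 arrays of the time 95 and 0, and without the filter 51 on array B.

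**Figure D2:**
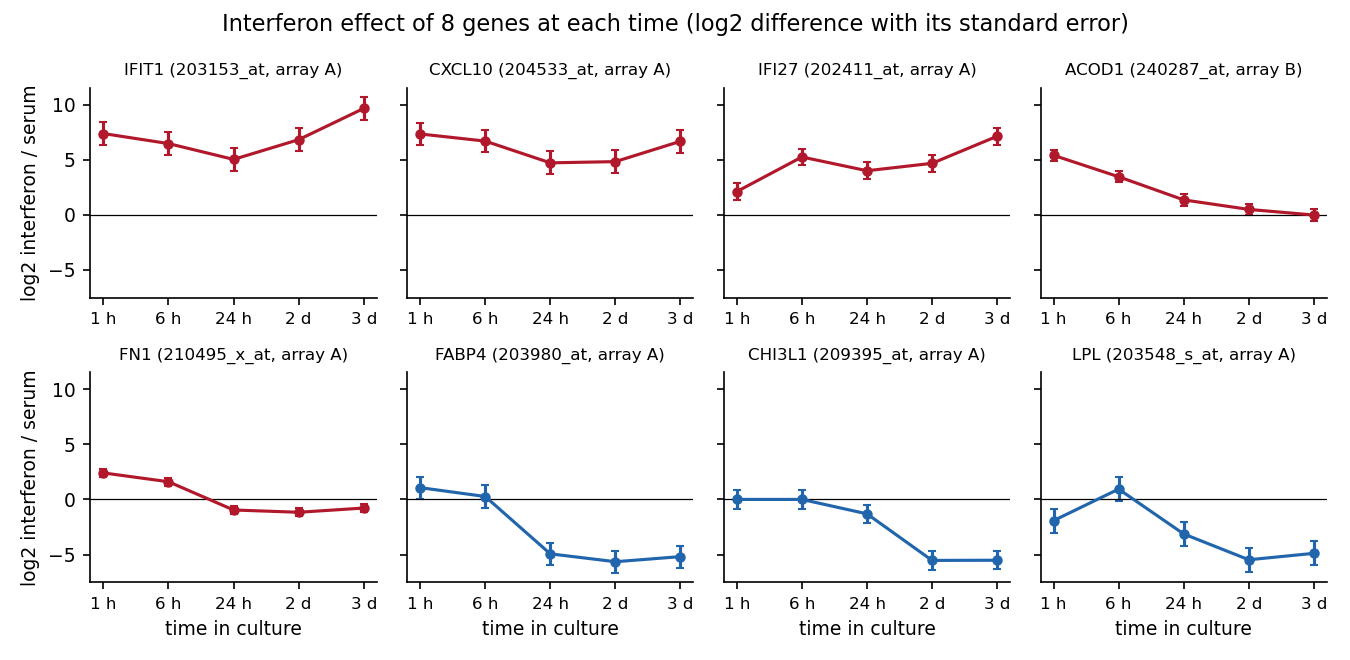
Interferon effect of 8 genes at each time, as the log2 difference between interferon and serum with its standard error (n = 2 samples per group), above 0 where interferon was higher. IFIT1 stayed between 5.03 and 9.66 throughout, ACOD1 went from 5.40 at 1 hour to -0.02 at 3 days, and FABP4, CHI3L1 and LPL stood at -5.19, -5.52 and -4.89 at 3 days.

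The average over the 5 times sets 10 samples against 10, but these come from only 2 culture sets. The model treats the times as separate samples, so its standard errors do not measure spread between volunteers or further culture sets. In this average interferon raised RSAD2 (7.07 ± 0.46, 134-fold), IFIT1 (7.07 ± 0.46, 134-fold) and ISG20 (6.09 ± 0.50, 68.0-fold). Interferon raised IFI44L (5.79 ± 0.45, 55.4-fold), USP18 (5.29 ± 0.30, 39.2-fold) and IFITM1 (5.27 ± 0.44, 38.5-fold) too. It also raised ISG15 (5.04 ± 0.32, 32.9-fold), TNFSF10 (4.70 ± 0.34, 25.9-fold) and, among the chemokines, CCL8 (6.26 ± 0.40, 76.8-fold) and CXCL10 (6.05 ± 0.46, 66.3-fold). On array B the highest were RSAD2, IFIT3 (5.57 ± 0.23, 47.6-fold), GBP5 (4.72 ± 0.31, 26.3-fold), IFIT2 and SAMD9L (4.18 ± 0.21, 18.1-fold). The strongest falls were smaller. They included CLEC5A (-2.91 ± 0.26, 7.52-fold lower), the kinase MATK (-2.49 ± 0.32, 5.63-fold lower), the gelatinase MMP9 (-2.37 ± 0.41, 5.16-fold lower) and the neutrophil attractant CXCL3 (-2.23 ± 0.43, 4.68-fold lower). On array B they included the aminotransferase BCAT1 (-2.37 ± 0.27, 5.17-fold lower), PHLDA1 (-2.29 ± 0.28, 4.91-fold lower), LINC01503 (-2.25 ± 0.40, 4.77-fold lower), RFLNB (-2.20 ± 0.22, 4.58-fold lower) and MCEMP1 (-2.12 ± 0.25, 4.34-fold lower). NRP1 (-2.48 ± 0.49, 5.59-fold lower), LPL (-2.32 ± 0.38, 5.00-fold lower) and ABCC3 (-2.20 ± 0.54, 4.58-fold lower) fell too, but without set 2 they stood at -1.44, adjusted p = 0.103, -1.29, adjusted p = 0.324 and -1.36, adjusted p = 0.162. FLRT2 (-2.21 ± 0.38, 4.61-fold lower) lost its call without either set (-2.21, adjusted p = 0.0512 without set 1; -2.19, adjusted p = 0.122 without set 2). Without the 8 arrays of 2 and 3 days MATK stood at -1.64, adjusted p = 0.0659, MMP9 at -1.97, adjusted p = 0.0740, CXCL3 at -2.31, adjusted p = 0.0758 and LINC01503 at -2.10, adjusted p = 0.0661, and NRP1, LPL, FLRT2 and ABCC3 between -1.92 and -1.04 (adjusted p 0.123 to 0.234). NRP1 and ABCC3 also lost their call without the 3 samples of highest GAPDH ratio (0.0514 and 0.0509), and ABCC3 without the filter (0.0717) or the 24 hour arrays (0.0641).

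In the average over times, 56 of 57 interferon-stimulated genes rose and all 57 did when adjusted over the list alone (median 3.23; camera adjusted p = 7.66e-103, and 0.00587 with an estimated correlation). The MHC class I list had 10 of 19 risen (11 over the list alone), led by TAP1 (2.03 ± 0.18), NLRC5 (1.78 ± 0.19) and the immunoproteasome subunits PSMB9 (1.68 ± 0.24) and PSMB8 (0.98 ± 0.17). That list had an adjusted p of 2.25e-09, or 0.0103 with an estimated correlation. The MHC class II list had 1 of 13 risen (1 over the list alone), HLA-DOB, which restrains peptide loading (1.86 ± 0.29). Its median was -0.02 and its adjusted p 0.875. Sensors counted 14 risen of 31 (18 over the list alone), with RIGI at 4.60 ± 0.36, IFIH1 at 3.19 ± 0.23, ZBP1 at 3.19 ± 0.33 and AIM2 at 2.41 ± 0.30 (adjusted p = 4.13e-15; 0.0103 with an estimated correlation). Chemokines counted 5 risen of 8 (5 over the list alone), with an adjusted p of 8.66e-09, or 0.0114 with an estimated correlation. Cell death genes counted 9 risen of 28 (15 over the list alone), TNFSF10, XAF1 (3.26 ± 0.24) and FAS (1.67 ± 0.23) among them (adjusted p = 3.25e-08; 0.0128 with an estimated correlation). The tryptophan, arginine and NAD list had 5 of 13 risen (6 over the list alone), IDO1 (3.54 ± 0.42) and GCH1 (3.49 ± 0.29) foremost (adjusted p = 8.24e-06; 0.0345 with an estimated correlation). The metallothioneins counted 4 risen of 6 (6 over the list alone), MT1H (2.08 ± 0.28) and MT2A (1.73 ± 0.19) among these near-identical copies (adjusted p = 3.25e-08; 0.0345 with an estimated correlation).

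For the other lists over all times the camera call, where there was one, did not hold with an estimated correlation. Interferon signalling counted 8 risen and 1 fallen of 23 (10 and 1 over the list alone), with IRF7 at 2.97 ± 0.26 and IRF2 at 1.47 ± 0.21 (adjusted p = 5.05e-06; adjusted p = 0.0527 with an estimated correlation). Anti-inflammatory and feedback genes had 7 risen of 15 (7 over the list alone), CD274 (3.60 ± 0.28) and IDO1 among them (adjusted p = 5.60e-04; adjusted p = 0.0912 with an estimated correlation). Lymphocyte-stimulating cytokines counted 6 up and 1 down of 15 (7 and 2 over the list alone), with TNFSF13B at 1.89 ± 0.21 (adjusted p = 9.55e-04; adjusted p = 0.0817 with an estimated correlation). The migratory dendritic cell list counted 6 up and 1 down of 20 (7 and 1 over the list alone), LAMP3 at 3.00 ± 0.40 (adjusted p = 0.00914; adjusted p = 0.145 with an estimated correlation). Heat shock genes had 2 risen of 10 (3 over the list alone; adjusted p = 6.89e-04, but adjusted p = 0.139 with an estimated correlation). Macrophage maturation genes had 14 fallen and 1 risen of 35 (17 and 2 over the list alone; median -0.62; adjusted p = 1.78e-05, but adjusted p = 0.208 with an estimated correlation). Respiratory chain subunits had 6 fallen of 20 (9 over the list alone; median -0.28; adjusted p = 5.59e-04, but adjusted p = 0.0926 with an estimated correlation). Cytosolic ribosomal proteins had 4 fallen of 17 (5 over the list alone; median -0.32; adjusted p = 1.69e-05, but adjusted p = 0.312 with an estimated correlation). The 18S ribosomal RNA control was lower with interferon by -0.60 on array A (10 of 10 pairs, exact permutation test, p = 0.00195, adjusted 0.0312). On array B, which measured the same RNA, it was lower by -0.51 (9 of 10 pairs, adjusted 0.0312). The 28S control gave no call in that test. It stood at -0.32 on array A (4 of 10 pairs higher, adjusted p = 0.361) and -0.27 on array B (5 of 10 pairs higher, adjusted p = 0.361). These 10 pairs come from only 2 culture sets. A link between the RNA controls and the ribosomal protein transcripts was not tested.

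Several further lists did not pass the test as a whole over all times, which does not show that they stayed level. Inflammatory cytokines had 1 rise, TNFAIP6 (2.00 ± 0.35), and 2 falls, CXCL3 and IL18 (-1.43 ± 0.31; -1.33, adjusted p = 0.208 without set 2), of 17 (2 and 3 over the list alone; adjusted p = 0.328). Fc receptors and complement had 3 of 21 risen, SERPING1 (3.09 ± 0.24), CFB (2.76 ± 0.36) and C3AR1 (0.76 ± 0.15). This made 3 up and 1 down over the list alone and an adjusted p of 0.286. Immediate-early genes had 4 rises, KLF6 (1.76 ± 0.23) among them, and 2 falls, of 23, MYC (-1.91 ± 0.36; -1.54, adjusted p = 0.225 without set 2) among the latter (4 and 3 over the list alone; adjusted p = 0.285). Adhesion and migration genes had 3 up and 6 down of 26 (3 and 8 over the list alone; adjusted p = 0.169). Cholesterol and lipid genes had 1 up and 4 down of 21, PLIN2 of lipid droplets at -0.83 ± 0.17 (2 and 7 over the list alone; adjusted p = 0.0950). Glycolysis and hypoxia had 3 up and 2 down of 23 (3 and 3 over the list alone; adjusted p = 0.875). Cell cycle genes had 4 up of 18, the inhibitor CDKN1A (1.16 ± 0.17) among them (4 over the list alone; adjusted p = 0.122). Monocyte markers had 4 down of 18, CD93 at -2.15 ± 0.29 (4 over the list alone; adjusted p = 0.0777). Without the 8 arrays of 2 and 3 days IL18 (-1.28, adjusted p = 0.0780), CDKN1A (0.81, adjusted p = 0.107) and PLIN2 (-0.84, adjusted p = 0.0716) lost their call, and PLIN2 also without the set as a block (adjusted p = 0.122).

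Among markers of other blood cells, platelet (adjusted p = 0.285), erythroid (0.619), neutrophil (0.619) and NK cell lists (0.169) had no member called over all times by limma, of 9, 6, 6 and 7 measured. T cell markers had 1 rise of 9, CCR7 (1.56 ± 0.44), whose call ended on leaving out either set or any of 10 single samples (1.28 to 1.66, adjusted p 0.0591 to 0.168). Basophil and mast cell markers had 1 fall of 5, GATA2 (-1.03 ± 0.24; -0.55, adjusted p = 0.342 without set 2), with adjusted p of 0.813 and 0.905 for the lists. B cell markers had 1 rise of 11 (adjusted p = 0.303): PAX5, a transcription factor of the B lineage (2.36 ± 0.27), while its companions on the list did not pass. Plasmacytoid dendritic cell markers had 3 rises and 1 fall of 8 (adjusted p = 0.0128; adjusted p = 0.0710 with an estimated correlation). These were IRF7, itself an interferon-induced gene, TCF4 (1.30 ± 0.31; 0.83, adjusted p = 0.168 without set 2) and the cytokine receptor IL3RA (1.55 ± 0.42), whose call ended on leaving out either set or any of 8 single samples (0.71 to 2.39, adjusted p 0.0503 to 0.304). The fall was NRP1, a receptor also made by macrophages. Without the 8 arrays of 2 and 3 days CCR7, GATA2, TCF4 and IL3RA lost their call (adjusted p 0.0738 to 0.258). Each also lost it in at least 2 other fits, CCR7 without the set as a block among these (adjusted p 0.0539 to 0.138 over these fits).

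In all, 721 probe sets were higher and 762 lower on array A over all times, and 411 and 357 on array B. With each array centred on its median the split on array A became 800 higher and 549 lower, and on array B 421 and 265. Leaving out set 1 gave 740 and 398 and leaving out set 2 gave 445 and 243. Without the 3 samples of highest GAPDH ratio 975 and 480 were called, without the 24 hour arrays 827 and 492, and without those of 2 and 3 days 493 (379 higher) and 268 (222 higher), all chosen after the data were seen. Without the set as a block 867 and 464 were called, and CXCL3 was lost (adjusted p = 0.0525). Moderation without the trend gave 420 on array B, and a minimum log2 difference of 1 left 647 and 427.

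Higher calls were shared between times far beyond what independent lists would give. The comparisons share the spread estimate of each probe set and the same 2 culture sets. Some overlap beyond independent lists can therefore arise without a shared response. Of 58 probe sets higher at 1 hour on array A, 52 were also among the 290 at 6 hours, where independent lists would share 1.11. Of 148 at 2 days 119 were among the 171 at 3 days (1.67 for independent lists). Of the 12 lower calls of 1 hour on array A 1 was shared with 6 hours (0.0688) and 0 with any later time, and of 18 on array B 0 with any other time. Between 2 and 3 days 37 of 78 lower calls were shared on array A (0.416). On array B 49 of 65 higher and 14 of 19 lower at 2 days were shared with 3 days (0.290 and 0.0339 for independent lists). On array A 35 probe sets were higher at all 5 times and none lower, and on array B 25 and none. Over all tested probe sets the interferon effects of the 2 culture sets correlated at 0.160 to 0.402 on array A and 0.101 to 0.173 on array B, depending on the time. A limma F test of differences between the 5 effects called 1 probe set on each array (854 and 1071 at an unadjusted p under 0.05). On array A it was FN1, fibronectin (adjusted p = 0.0274), with effects of 2.41, 1.60, -0.96, -1.17 and -0.78 from 1 hour to 3 days, each ± 0.35. The serum samples at 1 hour lay at the floor, so the first effect is at least 2.41, and 3 other fibronectin probe sets that rose in serum alone gave 0.00, -1.17 and 0.18 at 1 hour with adjusted F test p of 0.251, 0.35 and 0.286. On array B it was ACOD1 (adjusted p = 0.0152), with 5.40, 3.46, 1.36, 0.49 and -0.02, each ± 0.52. These counts of 1 became 0 without the set as a block and 12 and 7 with each pair as a block. On array A the count was 0 without any sample of 2 or 3 days, the interferon samples of 1 hour, the 1 hour serum sample of set 1 or the 6 hour interferon sample of set 2. It was 12 and 9 without the 24 hour serum samples of set 2 and set 1, 4 and 3 without the 24 hour interferon samples of set 1 and set 2, 6 without the 6 hour serum sample of set 2, and 3 without the 1 hour serum sample of set 2. On array B it was 18 without the 6 hour serum sample of set 2, 2 without the 6 hour interferon sample of set 2, either 24 hour serum sample or the 3 day serum sample of set 1, and 0 without the 1 hour serum sample of set 1, the 1 hour interferon sample of set 2, either 2 day serum sample, the 3 day serum sample of set 2 or either 3 day interferon sample. The difference of the interferon effect between the 2 sets gave no call by limma on either array (1237 and 1139 at an unadjusted p under 0.05); it gave 1 on array A without any of the 4 samples of 3 days and 1 on array B without any of the 4 samples of 1 hour.

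The serum cultures changed by themselves, which is the background of every interferon comparison. From 1 to 6 hours the cystine transporter SLC7A11 (6.70 ± 1.00, 104-fold), the oxidoreductase NQO1 (5.26 ± 0.47, 38.4-fold), malic enzyme ME1 (5.16 ± 0.78, 35.7-fold), DOCK4 (5.60 ± 0.43, 48.4-fold), WNT5A (5.00 ± 0.80, 32.1-fold) and FN1 (5.32 ± 0.35, at least 39.9-fold) rose. Of 5 other FN1 probe sets 2 were slightly below 0. On array B SLC41A2 (5.95 ± 0.70, at least 61.9-fold), the phosphodiesterase PDE7A (5.11 ± 0.61, 34.5-fold) and ABCC3 (5.05 ± 0.72, 33.2-fold) rose. MTARC1 (-5.03 ± 0.63, 32.6-fold lower), the oxysterol receptor GPR183 (-4.28 ± 0.55, 19.5-fold lower), PDE4D (-4.19 ± 0.68, 18.3-fold lower), RIPOR2 (-4.19 ± 0.44, 18.2-fold lower), ANKRD9 (-4.13 ± 0.62, 17.5-fold lower) and ANKRD22 (-4.01 ± 0.62, 16.1-fold lower) fell. NR4A2, an immediate-early nuclear receptor, fell (-5.04 ± 0.92, 32.9-fold lower), a call lost without the 1 hour sample of set 1 (-4.24, adjusted p = 0.123) or the 6 hour sample of set 2 (-3.95, adjusted p = 0.0539). Immediate-early genes had 10 of 23 fallen, and 18 over the list alone (median -1.91, adjusted p = 1.26e-12; adjusted p = 0.361 with an estimated correlation). Macrophage maturation genes had 4 risen and 1 fallen of 35 (6 and 1 over the list alone; median 0.83, adjusted p = 3.23e-04; adjusted p = 0.361 with an estimated correlation), FABP5 (3.51 ± 0.54) and CD9 (3.41 ± 0.51) among those that rose. On array A 320 probe sets were higher and 236 lower, 380 and 175 with each array centred on its median, and on array B 121 and 152. The 1 hour sample of set 1 carried much of this: without it 106 and 66 were called. On array A 369 were called without the 1 hour sample of set 2 and 198 without the 6 hour sample of set 1. Without the set as a block 166 and 96 were called, and 3 of the 22 genes picked by rule lost their call. Without the trend 285 and 39 were called, and without the filter 133 on array B.

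By 3 days without interferon several macrophage transcripts were far higher. FN1 (9.83 ± 0.35, at least 907-fold), FABP4 (8.04 ± 1.00, at least 263-fold), the selenium carrier SELENOP (7.83 ± 0.80, at least 227-fold), CHI3L1 (7.69 ± 0.79, at least 206-fold), GPNMB (7.33 ± 0.49, 161-fold), the apolipoproteins APOE (7.33 ± 0.95, at least 161-fold) and APOC1 (7.31 ± 0.81, 159-fold) and the protease inhibitor A2M (7.12 ± 0.95, 139-fold) rose. On array B so did the formyl peptide receptor FPR3 (5.66 ± 0.40, 50.7-fold) and KCNJ5 (5.55 ± 0.75, at least 46.8-fold). Of 2 other CHI3L1 probe sets 1 went the other way. FOSB (-9.14 ± 1.48, 565-fold lower), the neutrophil attractant CXCL8 (-7.66 ± 0.86, 202-fold lower), properdin CFP (-7.49 ± 0.84, 180-fold lower), interleukin IL1B (-6.76 ± 0.96, 108-fold lower), HCAR3 (-6.71 ± 0.44, 105-fold lower), NR4A2 (-6.01 ± 0.84, 64.4-fold lower) and pentraxin PTX3 (-5.77 ± 0.69, 54.5-fold lower) fell, with GLT1D1 (-5.68 ± 0.68, 51.2-fold lower), GBP2 (-4.99 ± 0.46, 31.9-fold lower) and VSTM1 (-4.99 ± 0.83, 31.8-fold lower) on array B. CCL20 fell (-6.89 ± 1.34, at least 118-fold lower), a call lost without the 3 day sample of set 1 (-5.83, adjusted p = 0.0593).

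Of 35 macrophage maturation genes 26 rose in serum by 3 days (30 up and 1 down over the list alone; median 3.93, camera adjusted p = 2.74e-23; adjusted p = 0.0855 with an estimated correlation). Of 17 inflammatory cytokines 11 fell (13 over the list alone; median -4.08, adjusted p = 1.35e-12; adjusted p = 0.1 with an estimated correlation). Of 23 immediate-early genes 16 did (20 over the list alone; median -2.46, adjusted p = 5.39e-19; adjusted p = 0.1 with an estimated correlation). Monocyte markers had 6 falls and 1 rise of 18 (6 and 1 over the list alone; adjusted p = 3.63e-05; adjusted p = 0.155 with an estimated correlation). Among those that fell were S100A12 (-5.06 ± 0.48), TREM1 (-5.04 ± 0.60), S100A9 (-4.05 ± 0.51) and S100A8 (-3.43 ± 0.45). Interferon-stimulated genes had 12 falls and 1 rise of 57 in serum alone (17 and 2 over the list alone; median -0.90, adjusted p = 2.74e-06; adjusted p = 0.399 with an estimated correlation). On array A 860 probe sets were higher and 635 lower, and on array B 452 and 400. With each array centred on its median the split on array A was 669 higher and 688 lower, and with quantile normalization 786 and 740. Without single samples the counts were 634 and 293 (1 hour, set 1), 831 and 448 (1 hour, set 2), 720 and 300 (3 days, set 1), and 592 and 295 (3 days, set 2). A model with no block for sets called 763 and 379, and on array B 350 were called without the trend and 547 without the filter. The 28S ribosomal RNA control stood higher in late serum samples, going from a mean of 12.3 at 1 hour to 14.4 at 2 and 3 days on the log2 scale of array A. The GAPDH 3' over 5' ratio stood higher there as well, at 1.54 and 2.21 on array A and 1.66 and 2.26 on array B.

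**Figure D3:**
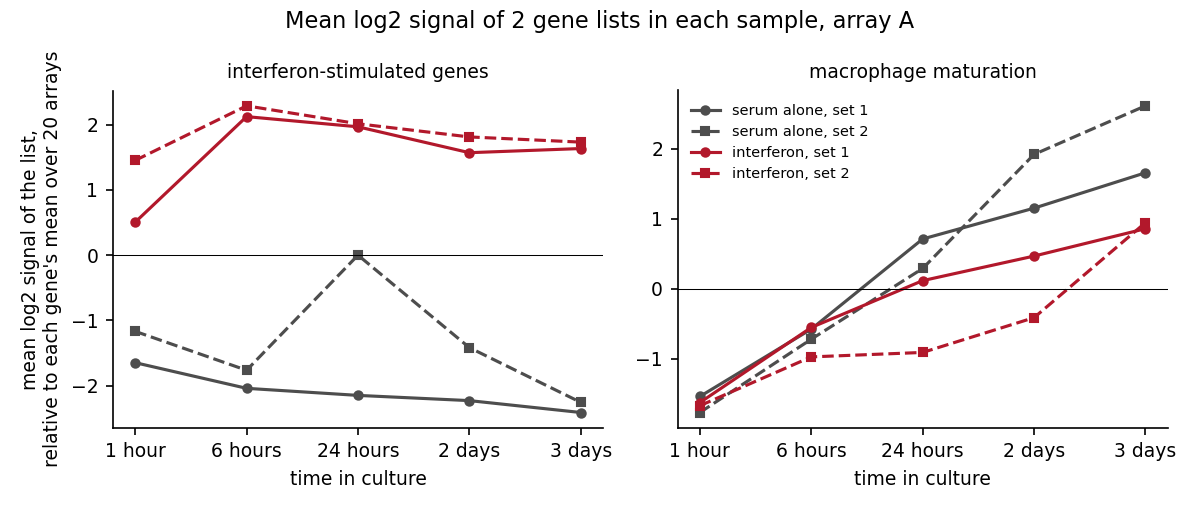
Mean log2 signal of the interferon-stimulated genes (left) and the macrophage maturation genes (right) in each of the 20 samples on array A, relative to each gene's mean over the 20 arrays; lines join the samples of one set and treatment over time. Interferon samples lay between 0.50 and 2.29 for the first list, and the serum sample of set 2 at 24 hours lay at -0.00 where that of set 1 lay at -2.15.

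**Figure D4:**
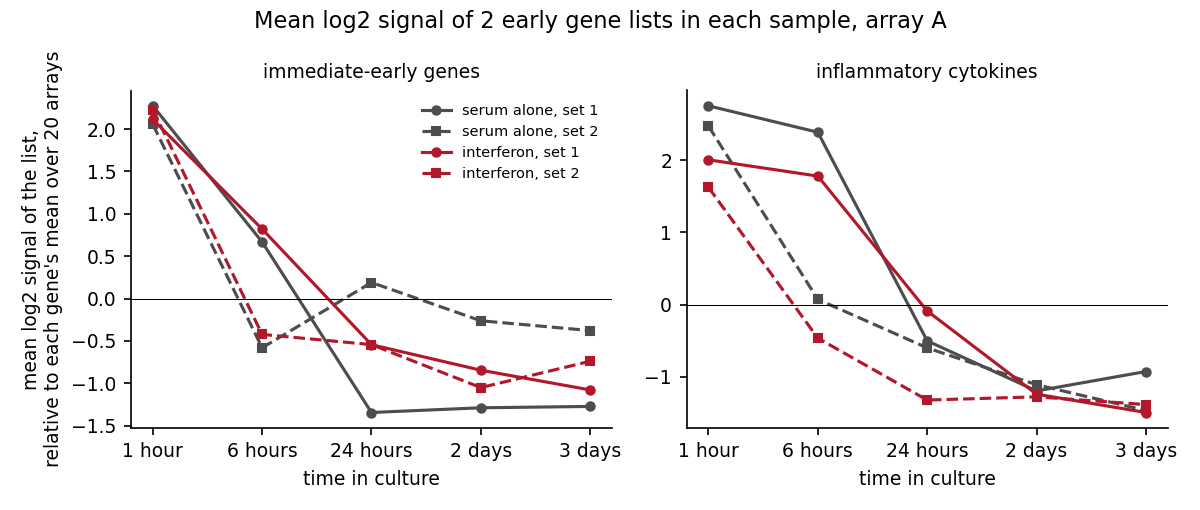
Mean log2 signal of the immediate-early genes (left) and the inflammatory cytokines (right) in each of the 20 samples on array A, drawn in the same way. In serum alone both lists were highest at 1 hour, and in set 2 the cytokines stood at 0.07 at 6 hours where those of set 1 stood at 2.39.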

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

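In this part the tests of exchanged labels, of a fault of array A, of the spread of shares within the list, of 3' bias, of scaling and of other splits of the samples were chosen only after the results were seen; the share outside the list and the test of a general delay were stated before their values were seen.

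In serum alone, the interferon-stimulated genes of set 2 at 24 hours lay at a mean log2 level of -0.000726, relative to the mean of all 20 arrays, with the next serum sample at -1.17, and 50 of 52 members on array A were higher than in set 1, by a median of 2.04. An exchange of labels with the interferon sample of the same set is argued against, since that sample lay 0.0464 above the interferon sample of set 1 where an exchange would put it far below. A fault of array A alone is argued against by a median difference of 1.40 over 23 members on array B. A candidate explanation that stays open is a share of material from the interferon culture: the share each of 45 members would need had an upper quartile 1.74 times the lower (0.129 to 0.225), and 80 interferon-induced probe sets outside the list gave a median of 0.168, within that range, though with a wider spread (2.83 times). Interferon made in or added to that culture at a low level stays open as well: the 1 hour response as a share of that at 6 hours was less even over the members (upper quartile 4.11 times the lower in set 1 and 3.46 in set 2), but an early response need not resemble a weak one at 24 hours, which was not tested.

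The median of the macrophage maturation genes was below 0 with interferon at 24 hours, 2 days and 3 days, with 2, 5 and 5 of 35 members called lower and an adjusted p = 0.286, 0.0810 and 0.182 for the list with an estimated correlation. Stronger 3' bias of interferon samples as the whole cause is argued against by set 1, where the list's median over these times was -0.49 although the GAPDH ratio was lower with interferon by -0.291, -0.425 and -0.466; in set 2, where the ratio was higher at 2 and 3 days, the median was -1.36, so a part of the size in set 2 could come from RNA quality. Scaling is argued against, since the list's median at 2 days was -1.25 or further from 0 with quantile normalization or median centring. Whether interferon delays the whole time course of the culture cannot be told apart from an effect on these genes: the 635 probe sets that fell in serum by 3 days had a median of 0.116 at 2 days with interferon, between the bounds set for either answer, while the 860 that rose had -0.226. An action of interferon on maturation itself was not tested and stays open.

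In every other split drawn, fewer probe sets were called over all times than with the real assignment. Most other splits place interferon and serum samples in the same group at some times, so a strong interferon effect can lower their counts. They therefore do not show how many of the single calls arose by chance. When 2 of the 4 arrays of each time were drawn as treated, 1 of 100 splits, the real one, gave as many calls as the 1483 of array A (highest other 680) or the 768 of array B (highest other 350). Among 100 exchanges within pairs, all parting the 10 pairs as the real assignment does, it was again 1, the real one, with 372 and 249 as the highest others. Most of the splits drawn over whole times part fewer pairs than the real one.

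The other results stand as values. Among interferon samples the interferon-stimulated genes of set 1 at 1 hour lay apart from the rest, at 0.504 with the nearest at 1.45. Nucleic acid and pathogen sensors in serum were lowest in set 1 at 6 hours, at -1.27 with the nearest at -0.66. Neutrophil markers with interferon were lowest in set 1 at 1 hour, at -0.713 with the nearest at -0.189. Chance sets apart about 1 in 20 groups, and 4 such samples in 64 groups compare with 3.2 by chance. FN1 (adjusted p = 0.0274 by limma's F test) and ACOD1 (adjusted p = 0.0152) passed the test of interferon effects that differ between times, but on array A the count of such probe sets was 0 with quantile normalization, median centring, a pseudocount, no trend or no block, and on array B 0 with median centring, no filter, the 75th percentile filter, no trend or no block.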

How the results depend on the processing

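In this part the exclusion of the 3 samples of highest GAPDH ratio, of 24 hours and of 2 and 3 days was chosen only after the data were seen; the other alternatives were set beforehand. Counts of calls are given for arrays A and B in this order. Moderation without the trend gave 43 and 33 at 1 hour, 235 and 78 at 6 hours, 89 and 0 at 24 hours, 140 and 18 at 2 days, 155 and 24 at 3 days, 420 on array B over all times, 285 and 39 for serum at 6 hours, 350 on array B for serum at 3 days, and 0 and 0 for the F test. No filter on dim probe sets gave 94 and 36 at 24 hours, 145 and 40 at 2 days, 51 on array B at 3 days, 133 and 547 on array B for serum at 6 hours and 3 days, and 19 and 0 for the F test. Only the 4 arrays of a time gave 57 on array B at 1 hour, 625 and 74 at 6 hours, 0 and 0 at 24 hours, 81 and 0 at 2 days and 95 and 0 at 3 days. A minimum log2 difference of 1 left 647 and 427 over all times. The F test gave 0 on array A with quantile normalization, 0 and 0 with median centring, 0 on array A with a pseudocount, 5 on array A with a floor at the 40th percentile and 0 on array B with a filter at the 75th percentile. The cause of these changes was not tested.

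Without culture set as a block the counts were 26 and 42 at 1 hour, 195 and 95 at 6 hours, 69 and 35 at 24 hours, 111 and 38 at 2 days, 117 and 41 at 3 days, 867 and 464 over all times, 166 and 96 for serum at 6 hours, 763 and 379 for serum at 3 days, and 0 and 0 for the F test. With each pair as a block they were 634 and 363 at 6 hours, 378 and 183 at 24 hours, 384 and 182 at 2 days, 431 and 207 at 3 days, and 12 and 7 for the F test. Of 465 calls of single genes 144 were lost without the block, and of 319 calls 1 was lost with each pair as a block. No filter ended 154 of the 465, no trend 126 and leaving out the 3 samples of highest GAPDH ratio 125, while only the 4 arrays of a time ended 96 of 212; no call of a single gene turned its direction. Among list results 1 call was lost and 2 were gained without the block. Without the 3 samples of highest GAPDH ratio the counts were 43 and 58 at 1 hour, 32 and 10 at 2 days, 109 and 46 at 3 days, 975 and 480 over all times, and 0 and 0 for the F test. Over all times 827 and 492 were called without 24 hours and 493 and 268 without 2 and 3 days.

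Leaving out 1 sample at a time, the counts on array A ranged from 15 to 79 at 1 hour, 212 to 385 at 6 hours, 11 to 229 at 24 hours, 84 to 273 at 2 days, 92 to 282 at 3 days, 1135 to 1661 over all times, 106 to 569 for serum at 6 hours and 592 to 1643 for serum at 3 days. On array B they ranged from 39 to 102, 120 to 202, 12 to 111, 28 to 123, 40 to 148, 574 to 782, 66 to 293 and 293 to 960. The F test ranged from 0 to 12 and 0 to 18 and the test between sets from 0 to 1 on both arrays. A set alone gave 740 and 398 (without set 1) and 445 and 243 (without set 2) over all times. The median of the interferon-stimulated genes ranged from 1.72 to 2.33 at 1 hour, 3.85 to 4.17 at 6 hours, 2.17 to 3.86 at 24 hours, 3.41 to 3.80 at 2 days, 3.60 to 4.21 at 3 days and 3.05 to 3.4 over all times. Of 256 list results 104 were called by camera; 83 of them were lost with an estimated correlation and 36 with fry, while quantile normalization changed 7 calls and median centring 3. The direction of 2 list medians turned: cytosolic ribosomal proteins with interferon at 2 days, to 0.0702 without the interferon sample of set 1 (range -0.618 to 0.0702), and heat shock genes with interferon at 3 days, to -0.131 without the serum sample of set 1 (range -0.131 to 0.563). Floor signals of 24 and 50.2 limit what can be said of dim transcripts, for which folds are lower bounds.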

Other observations

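Further genes changed in serum alone between 1 hour and 3 days. In the Fc receptor and complement list 6 of 21 rose, among them the inhibitory receptor FCGR2B (5.12 ± 0.64) and the complement genes C3 (4.47 ± 0.70) and C1QA (4.24 ± 0.65). Properdin was among the 3 that fell (8 and 3 adjusted over the list alone, list adjusted p = 0.636). GCH1 (-5.25 ± 0.65) and NAMPT, which makes a precursor of NAD (-3.85 ± 0.42), fell by 3 days, while KYNU of tryptophan breakdown was up at 6 hours (3.08 ± 0.32). In the glycolysis and hypoxia list 6 of 23 fell by 3 days and none rose (6 adjusted over the list alone). NDRG1, which hypoxia induces, was among them (-3.41 ± 0.33). The list's median was -0.53 (camera adjusted p = 1.30e-04; adjusted p = 0.155 with an estimated correlation). The sensor NLRP3 fell as well (-2.62 ± 0.45), as did the feedback inhibitors TNFAIP3 (-2.94 ± 0.46) and NFKBIA (-2.74 ± 0.39) of NF-kB signalling.

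Whether the interferon effect on a list differed between the 5 times was asked with an exact test over 945 arrangements of the 10 pairs. The 2 lowest of 32 lists were MHC class I presentation (exact p = 0.0106, adjusted 0.339), with mean effects of 0.14 at 1 hour and 0.92 at 6 hours, and heat shock genes (exact p = 0.0286, adjusted 0.457), with 1.45 at 6 hours and 0.00 at 24 hours. Neither passed the adjustment. The GAPDH 3' over 5' ratio gave no call between treatments in the exact sign-flip test (0.12 higher with interferon on array A, 6 of 10 pairs, p = 0.412).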
